A study of Mus musculus with 51 samples.

How the data were processed

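RNA from mouse fibroblasts, reprogramming cells, induced pluripotent stem cells (iPSC) and embryonic stem cells (ESC) was measured on 51 Illumina MouseRef-8 v2.0 beadarrays, which report 1 summarized bead brightness per probe. Per the labels' protocols, total RNA was extracted with the QIAGEN RNeasy kit, its quality was checked on an Agilent Bioanalyser and it was labelled with biotin. The labelling protocol and the scanner settings are not given in the sources used here. The intensity values the authors deposited are not normalized, since their medians per array ran from 108.7 to 212.11 and the lowest value was 63.3. With each intensity the authors deposited a detection p-value, which per the file headers belongs to the same array and gives the probe's standing against the array's background. A second set of intensity values that the authors deposited had already been scaled, with the same median (143.14) and the same mean (917.47) on every array. They kept the order of the probes within each array (lowest Spearman correlation 1), and the method behind them is not given in the sources used here. They served only as an alternative.

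Groups were taken from the submitters' labels. The reference groups were 2 fibroblast arrays (primary parental fibroblasts and day 0 of a secondary course), 6 clonal lines labelled F-class, 22 clonal lines described as C-class, 2 doxycycline-independent iPSC lines (1 from primary and 1 from secondary reprogramming) and 2 ESC arrays. The labels do not say how a clone was assigned to a class, so a class drawn from expression would not be independent of the values compared here. Single arrays covered clone 1 at day 30 and days 2, 5, 8, 11, 16 and 18 of the secondary course. The perturbation groups were 2 Tet-Myc lines with doxycycline and 48 h without it, and F-class cells at 0, 24 and 48 h of a histone deacetylase inhibitor (HDACi) that the labels do not name, with 2 arrays each. Nothing in the labels says that arrays of 1 group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical for ESC and HDACi. The number of arrays, 1 or 2 in every group but the clones at day 16, limits the precision.

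Intensities were background-corrected and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3, with negative controls inferred from the detection p-values and an offset of 16, and put on the log2 scale. Of 25697 probes, 23978 had 1 gene symbol in the platform annotation, 1719 had none and 0 had several. Each of 16593 genes was represented by its probe with the highest mean over all arrays. Entrez identifiers of 16582 genes matched a RefSeq table of assembly GRCm38.p6, used for names only, and 0 symbols changed. Where some but not all probes of a named gene passed the test, the gene is said to have probes that disagreed. Genes detected at p under 0.05 on at least 2 arrays of a fit were tested, or on at least 1 array for pairs of single arrays. Between 46.6% and 53.4% of probes were detected per array. A gene undetected on every array of 1 group has only a bound there. Its fold is given as "at least", from the brighter group's mean against, on each dimmer array, the higher of its own value and the lowest signal of a detected probe.

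Groups were compared with lmFit, contrasts and eBayes of limma, in 1 fit of the reference groups and 1 fit of the perturbation groups, two-sided. The p-values were adjusted by Benjamini-Hochberg over all genes tested, 11046 and 10154 genes, and called under 0.05. Folds and log2 fold changes are given with their standard error (SE), and group levels as mean ± SD of normalized log2 intensity. Groups of genes were tested with camera of limma, which compares a list with all other genes, at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The 21 lists fixed beforehand covered pluripotency, the reprogramming factors, fibroblast and mesenchyme, epithelial, adhesion and cytoskeleton, cell cycle, Myc and ribosome biogenesis, germline, trophoblast, endoderm, mesoderm, neural, p53 and senescence, interferon, ATF4 and heat-shock stress, immune and endothelial, glycolysis, oxidative phosphorylation, imprinted, DNA methylation and polycomb, and HDACi response genes. A further 4 lists of 200 genes each were taken from these arrays, namely the called genes with the largest fold change each way between F-class and ESC and between F-class and C-class clones, and were used only where neither of the groups they came from was compared. Counts "adjusted over the list alone" apply the adjustment to the members of 1 list. For pairs of single arrays there is no test, and a list's median difference is given with its percentile among 10000 random lists of the same size matched on mean level in 20 bins.

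Named genes followed a rule. It took the 10 called genes with the largest rise and the 10 with the largest fall per comparison, leaving out symbols that end in Rik, start with LOC or Gm and a digit, or are clone accessions. It added the 4 called members of each list with the largest change, or 2 members where none was called, and always Nanog, Zfp42, Esrrb, Dppa5a, Pou5f1, Sox2, Klf4, Myc, Cdh1, Epcam, Thy1 and Col1a1. Pairs of single arrays used the always-named genes and the 5 largest differences each way. Epcam had no named probe among the values used here. Probes for Pou5f1, Sox2, Klf4 and Myc may also read the transgenes. The comparisons, lists, named-gene rule and alternatives were chosen before the data were examined, except where the closing parts say otherwise.

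The Tet-Myc arrays with and without doxycycline carry the same line number, so the line pairs them by design. The deviations of same-numbered arrays from their group means correlated at 0.50 over genes, and the fit with the line as a block is given beside the results that it changes. The deposited intensity columns came in 2 number formats, 31 arrays with 1 decimal and 20 with more, and their background (5th percentile of intensity) ran from 80.4 to 98.9 and from 90.6 to 138. All clones, the primary fibroblasts and ESC replicate 1 had 1 decimal. The iPSC arrays, secondary fibroblasts and ESC replicate 2 had more, so number format was added as a term of the reference fit and is named where it ended a call. Within the reference groups only the ESC pair and the fibroblast pair held both formats. The term was thus estimated from these pairs alone and also takes up their other differences, such as cell source, so a call lost with it need not be due to format. Slides and scan dates are not given in the sources used here.

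The whole path from fit to calls was tested on simulated data made from the real means and spreads, with 200 genes changed per comparison. Noise was drawn independently for each gene, with 1 spread per gene shared by all groups. Correlated genes and spreads that differ between groups were thus not simulated, and the shares below hold for such data only. Of genes changed 2-fold, 88.1% were recovered for F-class against C-class, 50.7% for F-class and 67.2% for C-class against ESC, 53.7% and 68.7% against fibroblasts, 41.8% for iPSC against ESC and 61.2% for F-class against iPSC. The shares were 38.8% for Myc, 25.4% for HDACi at 24 h, 16.4% at 48 h and 29.9% for 48 h against 24 h. Of genes changed 4-fold, 98.5%, 90.9%, 93.9%, 89.4%, 84.8%, 89.4%, 90.9%, 77.3%, 83.3%, 72.7% and 69.7% were recovered in the same order, and of genes changed 1.5-fold, 70.1%, 17.9%, 35.8%, 23.9%, 29.9%, 5.97%, 23.9%, 2.99%, 4.48%, 2.99% and 0%. Between 1 and 10 unchanged genes were called per comparison, no call had the wrong sign, a list shifted by 1 log2 unit was found in every comparison, and at most 1 of 100 unshifted lists was called. Since the simulated genes were independent, this does not check the list test on correlated genes. Alternatives covered quantile normalization without background correction, the authors' scaled values, no detection filter and a stricter one (p under 0.01 on at least 3 arrays), the mean of a gene's probes, a 2-fold requirement, a variance for each group, fewer groups in a fit, a replicate block and leaving out single arrays. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.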

Results

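The 51 arrays follow mouse embryonic fibroblasts through reprogramming by c-Myc, Oct4, Sox2 and Klf4 under doxycycline control, and set them against their start, the fibroblast, and a pluripotent end point, the ESC. They hold 28 clonal lines at day 16, of which the labels call 6 F-class (clones 1, 2, 6, 7, 13 and 27) and 22 C-class, with 1 of these F-class lines again at day 30. The rest are 2 fibroblast arrays, a secondary course from cells already carrying the factors, 2 doxycycline-independent iPSC lines, 2 ESC arrays, 2 Tet-Myc lines with and without doxycycline, and F-class cells at 0, 24 and 48 h of an HDACi. Levels below are normalized log2 intensities given as mean ± SD, with n = 6 for F-class and n = 22 for C-class clones at day 16 and n = 2 for fibroblasts, iPSC, ESC and each Tet-Myc and HDACi group, while day 30 and each day of the secondary course after day 0 are single arrays. The Pearson correlation over genes averaged 0.9820 over 15 pairs of F-class clones and 0.9752 over 231 pairs of C-class clones. It was 0.948 for the ESC pair, 0.965 for fibroblasts, 0.988 for iPSC and 0.966 and 0.962 for the Tet-Myc lines with and without doxycycline, and it reached 0.995 in the HDACi groups. The ESC arrays differed by more than 2-fold at 1887 genes, against 265 for the iPSC pair. ESC replicate 1 stood apart in its immune and endothelial genes, whose mean was 10.80 there and 6.81 in replicate 2, and in its fibroblast genes, at 9.76 and 8.22.

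The first comparison asked how the classes of clone differ at day 16. Epithelial genes were lower in F-class than in C-class clones. Cdh1, the E-cadherin of epithelial junctions, stood at 9.41 ± 1.09 (SD, n = 6) in F-class against 11.33 ± 0.22 (SD, n = 22) in C-class clones, a log2 fold change of -1.93 (SE 0.23, adjusted p = 4.6e-07). The small GTPase Rab25 was 11.2-fold lower (adjusted p = 8.8e-07), the splicing regulator Esrp1 6.16-fold (adjusted p = 1.2e-08) and the tight-junction genes Cldn6 and Cldn4 9.12-fold and 6.06-fold lower. The adaptor gene Grb7 was 13.2-fold lower (log2 fold change -3.72, SE 0.41, adjusted p = 1.3e-07). In the other direction Neurog3, a transcription factor of endocrine progenitors, was 21.6-fold higher in F-class clones (10.39 ± 0.92 against 5.96 ± 1.47, adjusted p = 1.6e-06). Nkx2-3 was 12.2-fold higher, the laminin gene Lama1 7.50-fold, the neuroendocrine factor Insm1 5.85-fold and Hoxa9 5.59-fold.

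Of the 17 epithelial genes measured 16 fell and 0 rose, with the same counts adjusted over the list alone, and the list median was -1.93 (camera adjusted p = 1.0e-15, adjusted p = 0.0682 with an estimated correlation). Among 23 pluripotency genes 14 fell and 1 rose (16 and 1 adjusted over the list alone), with a median of -1.20 (camera adjusted p = 2.9e-08, adjusted p = 0.525 with an estimated correlation). Eras, a Ras-like gene of ESC, was 5.30-fold lower and the chromatin factor Utf1 5.26-fold lower (adjusted p = 6.7e-05 and 0.00029). Dppa5a was 11.5-fold lower, but with wide spreads of 2.90 and 2.58 (adjusted p = 0.018). The member that rose was Nanog, a core pluripotency factor, at 11.52 ± 0.25 in F-class and 9.73 ± 1.61 in C-class clones (log2 fold change 1.79, SE 0.61, adjusted p = 0.029). Esrrb and Zfp42 did not pass, with log2 fold changes of -1.64 (SE 0.72, adjusted p = 0.093) and -0.93 (SE 0.54, adjusted p = 0.22). Without clone 1, 2 or 7 the calls of Dppa5a (log2 fold change -2.88, -3.17 and -2.99) and Thy1 (-0.76, -0.81 and -0.74) ended. The Nanog call ended without clone 1, 2, 7 or 27, with the log2 fold change between 1.72 and 1.80.

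Adhesion and cytoskeleton genes were lower in F-class clones, with 8 of 22 falling and 1 rising (10 and 1 adjusted over the list alone) and a median of -0.33 (camera adjusted p = 0.00696, adjusted p = 0.778 with an estimated correlation). The integrin gene Itga3 was 7.13-fold lower and the focal-adhesion gene Zyx 2.09-fold lower. Fibroblast and mesenchyme genes went both ways, with 4 of 28 higher and 5 lower (4 and 6 adjusted over the list alone, camera adjusted p = 0.205). The repressors of Cdh1, Zeb2 and Zeb1, were 2.58-fold and 2.20-fold higher, whereas S100a4 was 2.46-fold lower and the surface marker Thy1 1.82-fold lower (adjusted p = 0.024). Col1a1 did not pass (log2 fold change -0.35, SE 0.31, adjusted p = 0.43). Of the reprogramming factors, Pou5f1 (-0.23, adjusted p = 0.62) and Klf4 (0.07, adjusted p = 0.87) did not pass. Myc was higher by 0.58 on the log2 scale (adjusted p = 0.025), a call that ended without clone 1 (log2 fold change 0.50) or clone 7 (0.46). Sox2 was 1.92-fold higher (adjusted p = 0.045) with probes that disagreed, and its call ended without any of clones 1, 2, 7, 13 and 27 (0.74 to 1.00).

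No other list fixed beforehand differed by camera. Germline genes had 3 of 11 members lower, among them Tex19.1 by 5.68-fold and Piwil2 by 4.23-fold. Of DNA methylation and polycomb genes 1 rose and 2 fell of 10, including the de novo methyltransferase Dnmt3b, 3.31-fold lower (adjusted p = 0.0006). Imprinted genes had 2 of 9 higher and 1 lower, with Peg10 2.64-fold higher. In the endoderm list, whose median of -0.01 and mean of 0.47 differ in sign, 2 of 7 rose, Lama1 and Hnf4a. The mesoderm list had 1 of 8 lower, Evx1 by 2.61-fold, and the stress list 1 of 9 lower, Hspa1a. In the p53 list 1 of 12 rose, Fas, and 3 fell. Cell cycle (2 higher and 1 lower of 19), Myc and ribosome biogenesis (2 higher of 20, 0 adjusted over the list alone), trophoblast (1 higher and 2 lower of 9, 1 and 3 adjusted over the list alone, median -0.46), neural (1 higher of 7), glycolysis (1 higher of 12) and oxidative phosphorylation genes (1 higher and 1 lower of 8) had few called members, which does not show equal levels. The HDACi response list had 1 lower of 6 (0 adjusted over the list alone), and interferon genes (0 of 7) and immune and endothelial genes (0 of 6) had no called member in limma. In all, 2727 of 11046 genes were called, 1553 higher and 1174 lower in F-class clones. With a 2-fold requirement 649 remained, 224 higher and 425 lower, which turned the share higher from 56.9% to 34.5%.

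**Figure D1:**
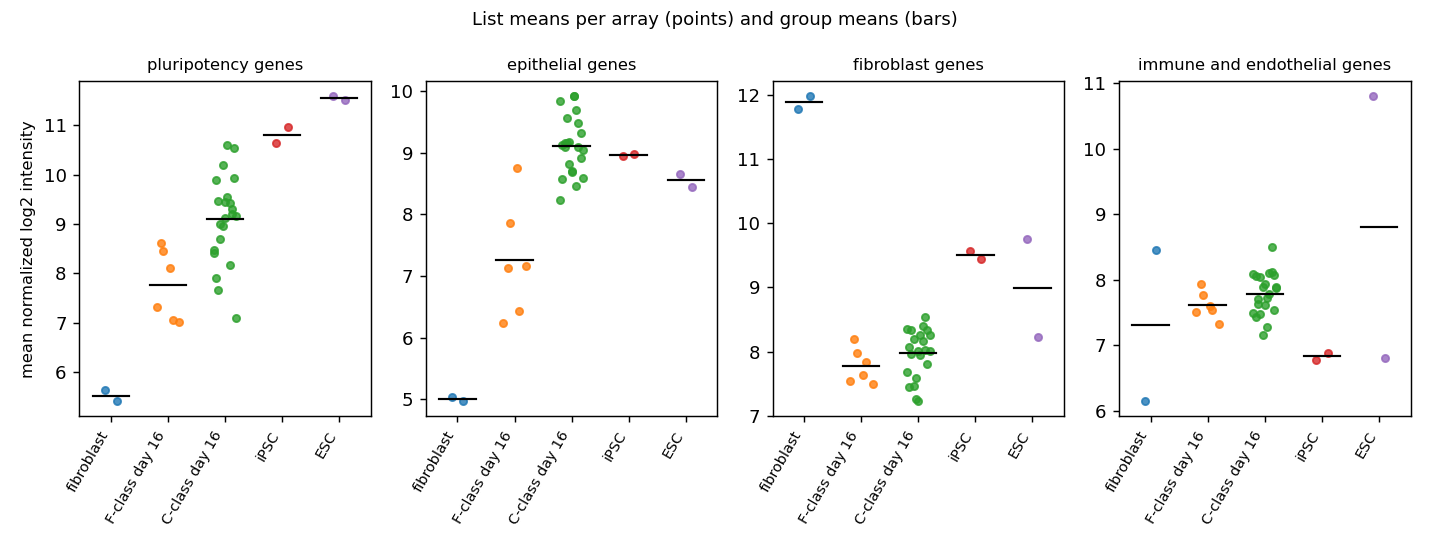
Mean normalized log2 intensity of the pluripotency, epithelial, fibroblast and immune lists on each array (points) of fibroblasts, F-class and C-class clones, iPSC and ESC, with group means as bars. The pluripotency means lie at 7.76 ± 0.72 (SD, n = 6) in F-class and 9.10 ± 0.90 (SD, n = 22) in C-class clones, below the ESC mean of 11.54, and the immune mean of ESC replicate 1 (10.80) lies above every other array drawn.

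Against fibroblasts, which asks what both classes left and gained, extracellular matrix and other fibroblast genes were far lower. Col1a1, the main collagen of fibroblasts, fell from 15.19 ± 0.48 (SD, n = 2) to 8.52 ± 0.53 (SD, n = 6) in F-class clones, a 102-fold drop (adjusted p = 4.2e-12), and 79.9-fold in C-class clones. The growth factor Ptn was 660-fold and 997-fold lower and the matrix gene Lum at least 134-fold and at least 143-fold lower. Thy1 was 21.7-fold and 11.9-fold lower. All 28 fibroblast and mesenchyme genes measured fell in F-class clones (28 adjusted over the list alone, median -4.43) and 27 in C-class clones (27, median -3.91). These shifts had camera adjusted p = 7.1e-15 and 2.0e-14 (adjusted p = 0.102 and 0.122 with an estimated correlation). The imprinted growth genes Igf2 and Dlk1 were 74.5-fold and 44.7-fold lower in F-class clones, within a list where 7 of 9 fell and 1 rose in both classes (camera adjusted p = 0.0111 and 0.00567, adjusted p = 0.240 and 0.195 with an estimated correlation). Adhesion genes fell at 15 of 22 members in both classes (medians -1.55 and -1.16, camera adjusted p = 5.6e-05 and 5.4e-04, adjusted p = 0.242 and 0.332 with an estimated correlation).

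Both classes gained Pou5f1, the gene of Oct4, at least 153-fold in F-class and at least 180-fold in C-class clones, and the zinc-finger factor Sall4 at least 91.1-fold and at least 138-fold. Nanog was 71.1-fold higher in F-class clones (log2 fold change 6.15, SE 1.08, adjusted p = 1.0e-05) and 20.6-fold higher in C-class clones (adjusted p = 0.00025). Dppa5a was at least 78.9-fold, Esrrb at least 14.0-fold and Zfp42 at least 6.76-fold higher in C-class clones. In F-class clones these 3 genes, undetected in fibroblasts, did not pass (at least 6.875-fold, 4.48-fold and 3.56-fold by their means, adjusted p = 0.14, 0.052 and 0.053). Pluripotency genes rose at 8 of 23 and fell at 2 in F-class clones (7 and 2 adjusted over the list alone, median 1.90) and rose at 20 and fell at 1 in C-class clones (median 3.88). The F-class shift had camera adjusted p = 0.0258 (adjusted p = 0.629 with an estimated correlation) and was no longer called with number format as a term, with quantile normalization, with the authors' values or under the stricter detection filter, and the C-class shift had adjusted p = 1.0e-04 (adjusted p = 0.332 with an estimated correlation). Cdh1 was 13.3-fold higher in F-class and 50.4-fold higher in C-class clones, Krt8 21.3-fold and 111-fold, and Cldn4 at least 14.0-fold and at least 84.6-fold. Epithelial genes rose at 11 of 17 in F-class clones (camera adjusted p = 0.00452, adjusted p = 0.466 with an estimated correlation) and at 17 of 17 in C-class clones (camera adjusted p = 3.8e-07, adjusted p = 0.184 with an estimated correlation).

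All 20 Myc and ribosome biogenesis genes rose against fibroblasts in F-class (median 1.65) and in C-class clones (median 1.52), with camera adjusted p = 1.7e-09 and 2.8e-09 (adjusted p = 0.0671 and 0.0729 with an estimated correlation). The nucleolar genes Ncl and Fbl were 5.72-fold and 4.75-fold higher in F-class clones. Cell cycle genes rose at 17 of 19 in F-class clones, with the replication gene Mcm7 6.71-fold higher, and rose at 17 and fell at 1 in C-class clones (camera adjusted p = 4.8e-06 and 2.7e-06, adjusted p = 0.163 and 0.172 with an estimated correlation). DNA methylation and polycomb genes rose at 7 and 8 of 10 (medians 0.98 and 1.16, camera adjusted p = 0.00739 and 0.00189, adjusted p = 0.163 and 0.133 with an estimated correlation). Oxidative phosphorylation genes rose at 7 and 8 of 8 (medians 0.60 and 0.63, camera adjusted p = 0.0111 and 0.00579, adjusted p = 0.0887 and 0.0729 with an estimated correlation). The glycolysis list rose at 8 of 12 in F-class clones (camera adjusted p = 0.0319, adjusted p = 0.629 with an estimated correlation), a call lost with number format as a term and without fibroblast replicate 2 (median 0.23), and did not pass in C-class clones (adjusted p = 0.0679). The stress genes Ddit3 and Chac1 were 16.8-fold and 17.5-fold lower in F-class clones and the interferon-induced Isg15 20.9-fold lower, while their lists were not called. Tek, an endothelial receptor gene, was 15.5-fold higher in F-class clones, and the immune list mean differed between the fibroblast arrays (6.15 and 8.46). F-class clones differed from fibroblasts at 6486 genes, 3480 higher and 3006 lower, and C-class clones at 6633, 3487 higher and 3146 lower. The 200 genes highest in F-class over ESC, chosen on these arrays and so not independent evidence of a direction, had 134 higher and 12 lower in C-class clones than in fibroblasts (138 and 13 adjusted over the list alone, camera adjusted p = 2.1e-09, adjusted p = 0.297 with an estimated correlation). The opposite 200, chosen in the same way, had 55 each way, with median 0.42, mean 0.24 and a test pointing lower (adjusted p = 0.82).

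Against ESC the question was how far each class had come to the pluripotent pattern. Nanog was 11.52 ± 0.25 (SD, n = 6) in F-class clones and 12.42 ± 0.26 (SD, n = 2) in ESC, and every F-class clone (at most 11.85) lay below both ESC arrays (at least 12.24). The difference did not pass (log2 fold change -0.90, SE 1.08, adjusted p = 0.52) in a fit whose variance is pooled with the C-class clones (SD 1.61), which does not show equal levels. Pou5f1 did not pass either (-0.69, adjusted p = 0.30). Dppa5a was 190-fold lower (8.30 ± 2.90 against 15.86 ± 0.02, adjusted p = 0.0019), Dnmt3l, a cofactor of DNA methylation, 168-fold, the E3 ligase gene Fbxo15 69.2-fold (adjusted p = 2.1e-07), the nuclear receptor Esrrb 59.4-fold (adjusted p = 0.00033), Zfp42 41.6-fold (adjusted p = 3.2e-05) and Sox2 7.70-fold (adjusted p = 0.00023). In C-class clones Fbxo15 was 49.7-fold, Klf2 30.1-fold, Zfp42 21.9-fold, Esrrb 19.0-fold and Sox2 14.8-fold lower than in ESC. Nanog was 6.44-fold lower in C-class clones (log2 fold change -2.69, SE 0.97, adjusted p = 0.024), a call that ended with number format as a term and without ESC replicate 1 (-2.87) or 2 (-2.50). Dppa5a did not pass there (-4.05, adjusted p = 0.061). Pluripotency genes fell at 19 of 23 in F-class clones (21 adjusted over the list alone, median -3.82, camera adjusted p = 1.6e-07) and fell at 16 and rose at 1 in C-class clones (17 and 1 adjusted over the list alone, median -2.44, camera adjusted p = 3.6e-04). Both calls were lost with an estimated correlation (adjusted p = 0.512 and 0.440).

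The keratinocyte gene Krtdap was at least 199-fold higher in F-class and at least 217-fold higher in C-class clones than in ESC, and the basal keratin Krt14 35.5-fold and 144-fold higher. The actin regulator Avil was at least 70.6-fold and Nkx2-3 43.6-fold higher in F-class clones. Cdh1 was 4.11-fold lower in F-class clones (log2 fold change -2.04, SE 0.41, adjusted p = 0.00014) and did not pass in C-class clones (-0.12, adjusted p = 0.82). Epithelial genes fell at 6 of 17 in F-class clones (camera adjusted p = 0.049996, adjusted p = 0.512 with an estimated correlation), a call lost without ESC replicate 1 (median -1.01) or 2 (-0.57), whereas 7 rose and 1 fell in C-class clones (9 and 1 adjusted over the list alone, camera adjusted p = 0.187). The mitotic kinase gene Plk1 was 19.8-fold and 16.9-fold lower (adjusted p = 8.5e-09 for F-class), and the cell cycle list fell at 12 and rose at 2 of 19 in C-class clones (camera adjusted p = 0.0146, adjusted p = 0.440 with an estimated correlation), a call lost without ESC replicate 2 (median -0.14). The cyclin-dependent kinase inhibitors Cdkn1a and Cdkn2a were 3.65-fold and 5.60-fold higher in F-class clones. The p53 list rose at 6 and fell at 1 of 12 in F-class clones (camera adjusted p = 0.0836) and rose at 8 in C-class clones (camera adjusted p = 0.0199, adjusted p = 0.440 with an estimated correlation), a call lost without ESC replicate 1 (median 0.58). Germline genes fell at 8 and 7 of 11 (camera adjusted p = 3.6e-05 and 3.6e-04, adjusted p = 0.329 and 0.440 with an estimated correlation), with Tex19.1 22.0-fold lower in F-class clones and the 2-cell-stage gene Zscan4c at least 59.4-fold lower.

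Fibroblast and mesenchyme genes fell at 14 of 28 in both classes against ESC (medians -1.27 and -1.09, camera adjusted p = 8.3e-04 and 0.00164, adjusted p = 0.512 and 0.440 with an estimated correlation). Both calls ended without ESC replicate 1 (medians -0.44 and -0.03), whose fibroblast list mean was 9.76 against 8.22 in replicate 2. Adhesion genes fell at 8 of 22 in F-class clones (camera adjusted p = 0.0434, adjusted p = 0.512 with an estimated correlation), lost without ESC replicate 1 (median -0.39). The immune and endothelial list had 1 of 6 higher, Tek, and 3 lower in each class (medians -2.04 and -1.46, not called). The 3 lower genes, Cd52, Tyrobp and Adgre1, lost their calls without ESC replicate 1, where the list mean was 10.80 against 6.81. Glycolysis genes fell at 7 of 12 in C-class clones (camera adjusted p = 0.0146, adjusted p = 0.440 with an estimated correlation), lost without ESC replicate 1 (median -0.30), and the glucose transporter Slc2a1 was 4.07-fold lower in F-class clones. Imprinted genes fell at 6 of 9 in both classes (camera adjusted p = 0.049996 and 0.0146, adjusted p = 0.512 and 0.440 with an estimated correlation), and both calls were lost with number format as a term and without ESC replicate 2 (medians -0.97 and -1.01). In all, 5299 genes differed between F-class clones and ESC, 2809 higher and 2490 lower. For C-class clones 4984 differed, 2521 higher and 2463 lower, falling to 1335 with a variance for each group (583 higher and 752 lower). With a 2-fold requirement 867 were higher and 1237 lower.

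The iPSC, which keep their state without doxycycline, were set against ESC and against the doxycycline-maintained F-class clones. Of 23 pluripotency genes 1 fell against ESC and 22 did not pass, which with 2 arrays a side does not show equal levels. Dppa5a stood at 15.61 ± 0.32 (SD, n = 2) in iPSC and 15.86 ± 0.02 (SD, n = 2) in ESC, and the log2 fold change was -0.05 for Nanog, -0.87 for Zfp42 (adjusted p = 0.73) and -1.25 for Esrrb (adjusted p = 0.71). Sox2 was 9.30 in iPSC, 11.13 in ESC and 8.18 in F-class clones, with a log2 fold change of -1.83 against ESC (adjusted p = 0.13). Some genes of the primitive streak and early endoderm were higher in iPSC. The homeobox gene Lhx1 was 20.0-fold higher (9.63 ± 0.43 against 5.31 ± 0.89, adjusted p = 1.2e-11), Evx1 11.8-fold (adjusted p = 0.00016), Mixl1 at least 7.88-fold, Sox17 8.37-fold (adjusted p = 2.7e-14), Gata6 5.82-fold and Foxa2 at least 3.56-fold. The variance behind these p-values is pooled mostly from the clones, where Sox17, Mixl1 and Foxa2 had class means of 4.92 or lower. It may thus understate the spread of the iPSC arrays, which stood at 8.85 and 7.99 for Sox17. Fgf8 was 20.2-fold higher (adjusted p = 0.005), which ended without iPSC replicate 2 (log2 fold change 3.92). Mesoderm genes rose at 4 of 8 (5 adjusted over the list alone, median 2.39, camera adjusted p = 8.2e-04, adjusted p = 0.0155 with an estimated correlation), a call lost without ESC replicate 2 (median 1.54). Endoderm genes rose at 3 of 7, with a median of -0.16 but a mean of 0.80 and a test pointing higher (camera adjusted p = 9.3e-04, adjusted p = 0.0155 with an estimated correlation), also lost without ESC replicate 2 (median -0.51) and under the stricter detection filter. These are the only 2 of 84 list calls in all comparisons that held with an estimated correlation, which was taken from the same pooled fit. That correlation rests mostly on the clones, where the called members other than Evx1 had class means of 6.00 or lower. Holding there thus does not set these 2 calls above the rest.

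Lower in iPSC than in ESC were the basigin-family gene Emb by 42.8-fold (adjusted p = 1.9e-05), Chchd4 by 30.6-fold and Zscan4c by 18.3-fold (adjusted p = 2.7e-06). Germline genes fell at 5 of 11 (median -0.58, camera adjusted p = 9.2e-04, adjusted p = 0.286 with an estimated correlation), lost without ESC replicate 2 (median -0.30). Immune and endothelial genes fell at 2 of 6 (4 adjusted over the list alone, median -2.21, camera adjusted p = 0.0145, adjusted p = 0.494 with an estimated correlation). Without ESC replicate 1, whose list mean was 10.80 against 6.81 in replicate 2, this median was 0.08. Cd52 and Tyrobp were no longer called without it (log2 fold change -0.05 and 0.13), without either iPSC array (-2.24 or lower) or with number format as a term. The adhesion list, with 1 higher and 1 lower of 22, was called higher (median 0.60, camera adjusted p = 0.00423, adjusted p = 0.548 with an estimated correlation), lost without ESC replicate 2 (median 0.33). So was the fibroblast list, with 0 called members in limma (median 0.55, camera adjusted p = 0.0166, adjusted p = 0.586 with an estimated correlation), which turned to -0.01 without ESC replicate 2. The 200 genes highest in F-class over C-class clones had 5 higher and 1 lower and the opposite 200 had 3 higher, neither called, both chosen on these arrays. In all 900 genes differed, 406 higher and 494 lower in iPSC, but only 122 were called with a variance for each group. The count was 400 with number format as a term (334 in both), and 474, 2003, 389 and 425 without ESC replicate 1, ESC replicate 2, iPSC replicate 1 and iPSC replicate 2.

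F-class clones stood below iPSC in most of the pluripotency list, with 15 of 23 lower and 1 higher (median -2.93, camera adjusted p = 1.0e-04, adjusted p = 0.471 with an estimated correlation). Sp5 was 70.4-fold lower, Dppa3, a maternal factor, 48.98-fold, Klf2 35.002-fold and Zfp42 22.7-fold (adjusted p = 0.00022), while Nanog (log2 fold change -0.85) and Pou5f1 (-0.30) did not pass. The falls of Dppa5a (159-fold) and Esrrb (24.9-fold) passed (adjusted p = 0.0023 and 0.0028) but were lost with number format as a term. Fgf8 was at least 147-fold lower and Sox17 at least 6.99-fold lower, and endoderm genes fell at 4 and rose at 1 of 7 (camera adjusted p = 0.0142, adjusted p = 0.271 with an estimated correlation), a call lost under the stricter detection filter (median 0.16). Fibroblast genes fell at 20 of 28 (camera adjusted p = 1.1e-05), adhesion genes at 17 of 22 (6.5e-05), imprinted genes at 8 of 9 (0.00298) and epithelial genes at 11 of 17 (0.0068), with adjusted p = 0.471, 0.471, 0.369 and 0.556 with an estimated correlation. Germline genes fell at 6 of 11 (camera adjusted p = 0.0259, adjusted p = 0.471 with an estimated correlation), lost without iPSC replicate 1 (median -0.49) and with number format as a term. Col1a1 was 16.5-fold and Thy1 11.2-fold lower. Of the 200 genes most specific to fibroblasts against the clones, 86.5% and 84.5% were higher on the iPSC arrays than on ESC replicate 2. Whether RNA of fibroblasts in the iPSC samples adds to the falls of fibroblast genes was not tested. Krtdap was 83.5-fold, Insm1 69.3-fold and Neurog3 33.1-fold higher in F-class clones. All F-class clones and both iPSC arrays differ in number format. Of 5882 called genes, 2236 were also called with number format as a term, which called 2707. That term rests on the ESC and fibroblast pairs, which differ in more than format, so the lost calls cannot be put down to format.

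The design asks whether F-class cells kept for a longer time come to express ESC genes, and clone 1 was measured at days 16 and 30, with 1 array each and so no replicate check. It stayed at the F-class level. All 23 pluripotency genes measured lay below both ESC arrays at day 30, 13 of them inside the range of the 6 F-class clones at day 16, 8 below it and 2 above. Zfp42 was 7.13 at day 30 and 7.48 at day 16, against 12.69 and 12.76 in ESC, and Nanog was 11.69 and 11.55, against 12.24 and 12.60. Esrrb was not detected on either day. Dppa5a was at least 4.83-fold higher at day 30, at 8.04, against 15.85 and 15.87 in ESC. The pluripotency median differed by -0.07, at percentile 28.8 of matched random lists. Fibroblast genes had a median of -0.35 (percentile 0.01), glycolysis genes -0.31 (percentile 0) and epithelial genes -0.42 (percentile 0.93), and the reprogramming factors 0.63 (percentile 99.85). Trh, the thyrotropin-releasing hormone gene, was 7.25-fold lower and Slc2a6 5.46-fold higher. Of 8628 genes, 148 were over 2-fold higher and 193 over 2-fold lower.

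The secondary course, with 1 array a day from fibroblasts at day 0, shows which genes moved early and which late. The basal keratin gene Krt14 was at least 277-fold higher at day 2, at 13.55, and at least 1372-fold higher at day 5, at 15.86, and it was still at 13.22 on day 16. Cdh1 was at least 5.22-fold higher at day 2, at least 35.3-fold at day 8 and at least 6.55-fold at day 18. Nanog was 7.62-fold higher at day 2, 25.1-fold at day 8 and 100.3-fold at day 18. Pou5f1 was at least 4.34-fold higher at day 2 and at least 49.6-fold at day 11. Esrrb was undetected through day 8 and at 7.68 on day 11, and Zfp42 reached 6.51 by day 18, with ESC at 12.69 and 12.76. Col1a1 was 7.15-fold lower at day 2 and 22.4-fold lower at day 18.

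Over a fixed set of members, the epithelial list mean was 4.97 at day 0, 8.12 at day 5, 9.07 at day 8, 8.81 at day 11 and 6.86 at day 18. The trophoblast mean was 5.16 at day 0, 6.27 at day 8, 6.29 at day 11 and 5.91 at day 18, and the pluripotency mean 5.42, 6.29, 6.97 and 6.88 on the same days. Medians against day 0 cover members detected on at least 1 of the arrays compared, which can differ by day, so they are given for single days only. The pluripotency median at day 18 was 1.84, at percentile 100 of matched random lists. That median was 0.72 with quantile normalization alone and 0.53 with no detection filter. Fibroblast genes were lower from day 2 (-2.49), with 26 of 28 over 2-fold lower, to day 18 (-3.41). Cell cycle genes were higher at day 2 (1.15) and day 18 (1.64) but lower at day 8 (-0.48, percentile 2.82). Immune and endothelial medians were -2.11 at day 2 and -2.24 at day 18, against a day 0 array whose immune list mean (8.46) was above that of the other fibroblast array (6.15). From day 16 to day 18, both labelled F-class, 10 of 16 epithelial genes were over 2-fold lower (median -1.08, percentile 0), and Cdh1 was 2.60-fold lower. At day 18, 1912 of 9765 genes were over 2-fold higher and 1860 over 2-fold lower than at day 0. With 1 array a day none of these differences has a replicate check.

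**Figure D2:**
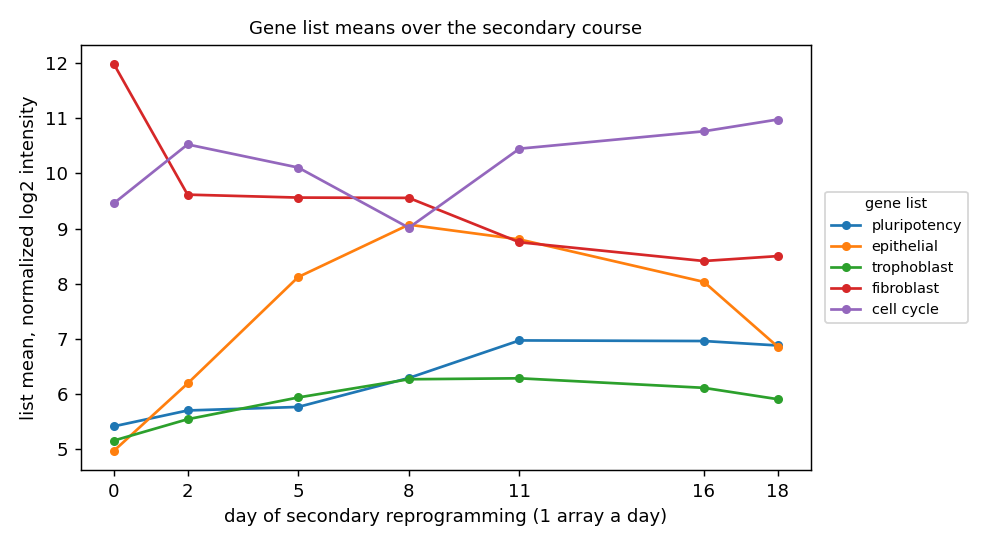
Mean normalized log2 intensity of the pluripotency, epithelial, trophoblast, fibroblast and cell cycle lists (lines) by day of the secondary course, 1 array a day, over the same list members on every day. The epithelial mean is 8.12 at day 5, 9.07 at day 8 and 6.86 at day 18, and the fibroblast mean goes from 11.985 at day 0 to 8.50 at day 18.

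Each array was placed between the classes by the share of 400 class genes (200 higher in each class, chosen on these clones) that lay nearer the F-class than the C-class mean. In the secondary course the share was 56.8% at day 2, 32.5% at day 8, 72.5% at day 16 and 92.8% at day 18. Clone 1 at day 30 had 97%, or 95.3% with means and lists that left out clone 1. Fibroblasts lay at 61.5% and 60.8%, iPSC at 40.3% and 36.8% and ESC at 34.8% and 38.3%. The fibroblast arrays lay nearer F-class at 41% and 41.5% of the genes higher in F-class clones. For the genes higher in C-class clones they did so at 82% and 80%, so their totals rest on the latter. Secondary day 2 had 47.5% and 66% for the 2 sets in that order. With means and lists made without it, each C-class clone lay between 2.00% and 40.5%, and the F-class clones lay at 92.0% (clone 1), 96.8% (clone 2), 72.0% (clone 6), 90.5% (clone 7), 50% (clone 13) and 86.3% (clone 27). F-class clone 13 had 70.5% for the genes higher in F-class and 29.5% for those higher in C-class clones, and it also had the highest Cdh1 of the 6, 10.98.

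**Figure D3:**
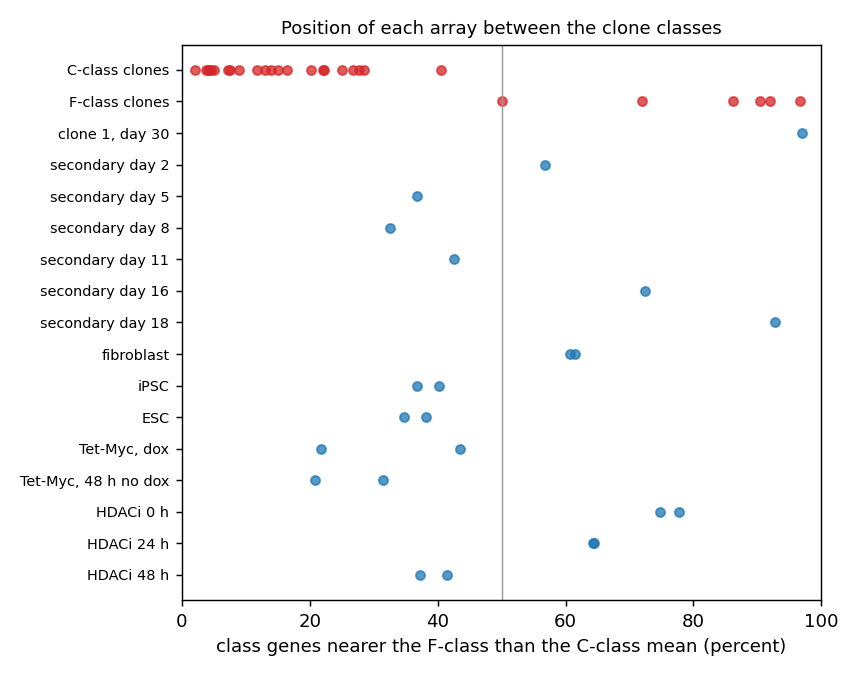
Percent of 400 class genes nearer the F-class than the C-class mean, 1 point per array, for the clones in red with means and lists made without the clone, and for other arrays in blue. C-class clones lie from 2.00% to 40.5%, secondary day 18 at 92.8% and HDACi-treated cells at 48 h at 41.5% and 37.3%.

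Tet-Myc lines were compared with doxycycline, labelled 0 h, and after 48 h without it. The labels name no array kept on doxycycline for 48 h, so withdrawal cannot be told apart from 48 h of further culture. The Myc probe itself did not pass (6.25 ± 0.45 without against 6.604 ± 0.33 with doxycycline, SD, n = 2 each, log2 fold change -0.36, adjusted p = 0.38). The fit shares its variance with the HDACi arrays. Over genes the difference within a pair had an SD of 0.68 and 0.72 for Tet-Myc and 0.27 to 0.31 for HDACi. Pooling may thus understate the Tet-Myc spread, and the 4 Tet-Myc arrays fitted alone, without the line as a block, gave 0 called genes in limma. In the pooled fit pluripotency genes were higher after 48 h without doxycycline. Zfp42 was 5.66-fold higher (9.31 ± 0.00 against 6.81 ± 0.83, adjusted p = 0.013) and Eras 3.10-fold (adjusted p = 0.017). Dnmt3b was 4.09-fold higher (adjusted p = 0.018), lost without line 1 on doxycycline (log2 fold change 1.81). Esrrb (log2 fold change 3.04, SE 0.91, adjusted p = 0.060) and Nanog (1.27, SE 0.39, adjusted p = 0.064) did not pass, Nanog did with the line as a block (adjusted p = 0.018), and so did Pou5f1 (0.55, adjusted p = 0.20 and blocked 0.040). The secreted TGF-beta antagonist Fst was at least 8.72-fold, the kinase gene Sgk1 15.2-fold and the immediate early gene Egr1 13.9-fold higher. The lysolipid transporter gene Mfsd2a was lower by 11.0-fold, the nucleoporin Nup210 by 9.25-fold, the serine synthesis enzyme Phgdh by 6.25-fold (adjusted p = 0.0027) and the glycolysis regulator Pdk1 by 4.89-fold. Cdkn2a was 3.47-fold lower (adjusted p = 0.0022).

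Of 23 pluripotency genes 11 rose and 0 fell (16 adjusted over the list alone, 16 with the line as a block), with a median of 1.41 (camera adjusted p = 4.5e-09, adjusted p = 0.177 with an estimated correlation). Myc and ribosome biogenesis genes fell at 3 of 20 (4 adjusted over the list alone), Cad, Ppan and Fbl (median -0.44, camera adjusted p = 0.0125, adjusted p = 0.507 with an estimated correlation). Glycolysis genes fell at 2 of 12 (6 adjusted over the list alone and 6 blocked, median -0.49, camera adjusted p = 0.00502, adjusted p = 0.426 with an estimated correlation). Adhesion genes rose at 3 of 21 (5 adjusted over the list alone and 8 blocked, camera adjusted p = 5.0e-04, adjusted p = 0.419 with an estimated correlation). Interferon genes rose at 4 of 7, with Oasl2 9.10-fold and Isg15 10.6-fold higher (camera adjusted p = 0.0329, adjusted p = 0.426 with an estimated correlation), and stress genes at 2 of 9 (camera adjusted p = 0.040027, adjusted p = 0.419 with an estimated correlation). Both calls ended with the line as a block (adjusted p = 0.0734 for each), and the interferon list mean without doxycycline was 9.12 in line 1 and 7.40 in line 2. Without line 1 on doxycycline the adhesion, ribosome, interferon and stress calls ended (medians 0.35, -0.41, 1.97 and 0.47), as did those of Cad, Ppan, Fbl and Isg15 (log2 fold change -0.96, -0.83, -0.60 and 2.67). Without line 1 off doxycycline the ribosome, interferon, stress and glycolysis calls ended (-0.27, 1.34, 0.28 and -0.26), and so did those of Ppan and Fbl (-0.64 and -0.53). Without line 2 off doxycycline the stress call ended (0.59). Cell cycle genes had 0 of 19 called in limma (camera adjusted p = 0.868), and epithelial genes 1 of 17 (camera adjusted p = 0.208).

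Of lists chosen on the clone and ESC arrays, and so not independent evidence of a direction, the genes higher in ESC than F-class had 64 of 189 higher and 1 lower (83 and 1 adjusted over the list alone, camera adjusted p = 3.0e-19, adjusted p = 0.419 with an estimated correlation). Those higher in F-class than ESC had 40 of 200 lower and 7 higher (camera adjusted p = 0.0024, adjusted p = 0.419 with an estimated correlation), lost without line 2 off doxycycline (median -0.23). Those higher in C-class than F-class had 38 of 193 higher and 4 lower (camera adjusted p = 7.0e-07, adjusted p = 0.507 with an estimated correlation), lost without line 1 on doxycycline (median 0.12). Those higher in F-class than C-class were not called (camera adjusted p = 0.208). In all 1553 of 10154 genes were called, 749 higher and 804 lower without doxycycline, with 2553 under the line as a block and 890 without line 1 on doxycycline. Fitting the 4 Tet-Myc arrays alone, without the line as a block and so ignoring the pairing, limma called 0 genes at an adjusted p under 0.05 and 1559 at an unadjusted p under 0.05.

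**Figure D4:**
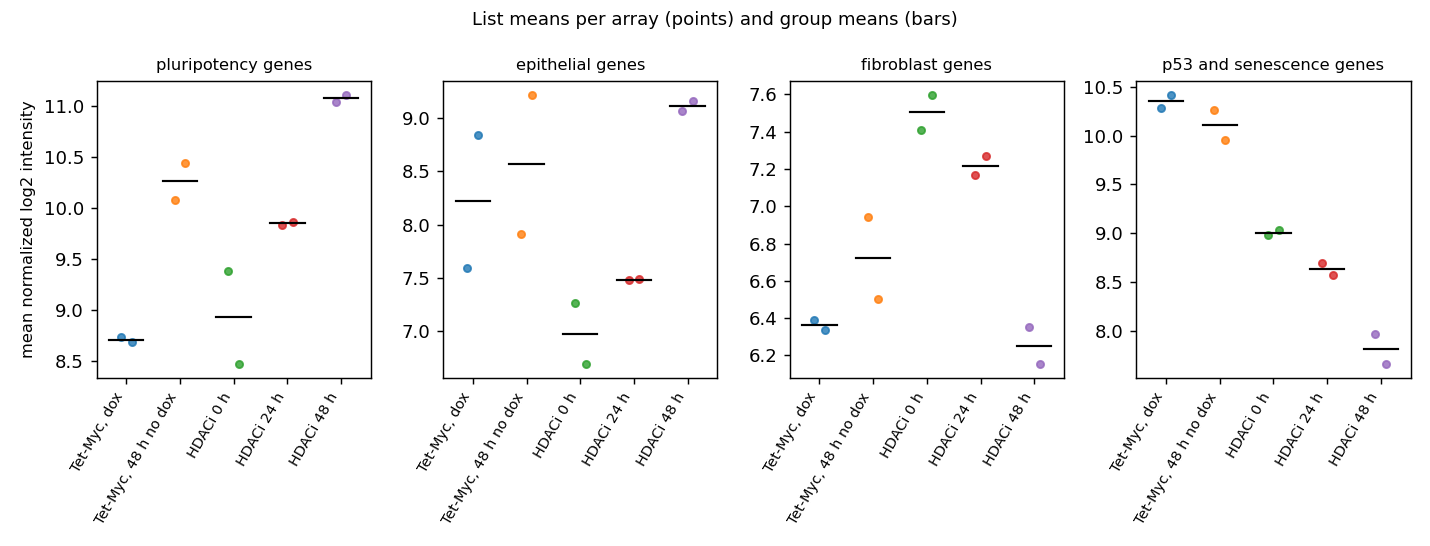
Mean normalized log2 intensity of the pluripotency, epithelial, fibroblast and p53 lists on each array (points) of the Tet-Myc and HDACi groups, with group means as bars. The pluripotency mean lies at 8.71 and 10.26 in Tet-Myc lines with and without doxycycline and at 8.93, 9.85 and 11.07 at 0, 24 and 48 h of HDACi.

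F-class cells given an HDACi were measured at 0, 24 and 48 h. The labels name no untreated array at 24 or 48 h, so the inhibitor cannot be told apart from time in culture. By 48 h pluripotency and epithelial genes stood far above 0 h. Utf1 rose 26.2-fold (10.89 ± 0.19 against 6.18 ± 1.09, SD, n = 2 each, adjusted p = 0.00088), Zfp42 10.2-fold (12.09 ± 0.04 against 8.74 ± 0.83, adjusted p = 0.0018), Dppa3 24.3-fold (adjusted p = 0.0045) and Sox2 4.29-fold (adjusted p = 0.00061). Esrrb reached 13.56 ± 0.03 from 8.82 ± 2.30 (26.8-fold, adjusted p = 0.0077) and Dppa5a 15.54 ± 0.02 from 9.77 ± 4.56 (54.5-fold, adjusted p = 0.037), where the 0 h arrays stood at 13.00 and 6.55. The Dppa5a call ended without either 48 h array (log2 fold change 5.78 and 5.76) and the Esrrb call without 48 h replicate 2 (4.73). Nanog (log2 fold change -0.02, adjusted p = 0.98) and Pou5f1 (0.20, adjusted p = 0.62) did not pass. Cldn6 rose 32.2-fold (adjusted p = 0.0033) and Krt18 9.04-fold. Cdh1 rose 4.35-fold (adjusted p = 0.0057), lost without 0 h replicate 2 (log2 fold change 1.91). Genes characteristic of the F-class clones fell, among them Neurog3 by 35.6-fold (12.36 ± 0.08 to 7.21 ± 2.29, adjusted p = 0.004) and Insm1 by 17.9-fold. Cdkn1a, which HDAC inhibitors often induce, was 11.1-fold lower at 48 h (adjusted p = 0.00052).

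Pluripotency genes rose at 14 of 23 (18 adjusted over the list alone, median 1.497), epithelial genes at 11 of 17 (14, median 2.14), cell cycle genes at 8 of 19 (10, median 0.63) and germline genes at 4 of 6 (4, median 3.53). The camera adjusted p values were 7.9e-07, 1.2e-05, 2.7e-04 and 4.6e-04 (adjusted p = 0.120, 0.349, 0.298 and 0.274 with an estimated correlation). The germline genes Tex19.1, Tex101 and Piwil2 were 19.8-fold, 18.1-fold and 16.7-fold higher. Fibroblast genes fell at 11 of 21 (median -1.24, camera adjusted p = 4.6e-06, adjusted p = 0.131 with an estimated correlation), with the crosslinking enzyme Lox 10.5-fold and Col1a1 4.58-fold lower. In the p53 and senescence list 7 of 11 fell (9 adjusted over the list alone, median -0.77, camera adjusted p = 2.3e-04, adjusted p = 0.144 with an estimated correlation). The HDACi response list had 1 higher, Mt2, and 1 lower, Cdkn1a (camera adjusted p = 0.563), and Mt2 lost its call without any of the 4 arrays (log2 fold change 1.77 to 2.06). Trophoblast genes rose at 4 of 9 and fell at 1, and DNA methylation and polycomb genes rose at 5 and fell at 1 of 10, with Dnmt3b 7.61-fold higher, neither list called (camera adjusted p = 0.119 and 0.0691). Genes higher in C-class than F-class clones, a list chosen on the clones and so not independent evidence of a direction, had 83 of 193 higher and 9 lower (100 and 10 adjusted over the list alone, median 1.32, camera adjusted p = 5.1e-11). Genes higher in F-class than C-class clones, chosen likewise, had 117 of 195 lower and 4 higher (134 and 9 adjusted over the list alone, median -1.496, camera adjusted p = 2.4e-21). Their adjusted p was 0.349 and 0.120 with an estimated correlation. Lists chosen from F-class against ESC had 117 of 189 higher and 6 lower for genes higher in ESC (camera adjusted p = 5.8e-19) and 104 of 200 lower and 11 higher for genes higher in F-class (camera adjusted p = 5.4e-16), with adjusted p = 0.217 and 0.120 with an estimated correlation. In all 2907 of 10154 genes were called at 48 h, 1439 higher and 1468 lower. The count was 1611, 1270, 1601 and 1227 without 0 h replicate 1, 0 h replicate 2, 48 h replicate 1 and 48 h replicate 2.

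At 24 h fewer genes were called in the pooled fit, of which 98 rose and 114 fell. Pooling with the Tet-Myc arrays, whose pairs differed more (SD 0.68 and 0.72 against 0.27 to 0.31), may overstate the HDACi spread. The HDACi arrays fitted alone called 1756 genes at 24 h and 4997 at 48 h. The methyltransferase-like gene Mettl7b was 6.63-fold higher (7.99 ± 0.08 against 5.26 ± 0.33, adjusted p = 0.022), and the replication genes Mcm5 and Mcm2 rose by 1.09 and 1.03 on the log2 scale (adjusted p = 0.026 and 0.021). Gdf3 rose 2.89-fold and L1td1 2.09-fold, and the acyl-CoA synthetase gene Acsl6 was 14.0-fold lower. Cell cycle genes rose at 6 of 19 (12 adjusted over the list alone, median 0.75, camera adjusted p = 9.8e-11, adjusted p = 0.180 with an estimated correlation) and pluripotency genes at 3 of 23 (6 adjusted over the list alone, median 0.84, camera adjusted p = 2.0e-07, adjusted p = 0.180 with an estimated correlation). DNA methylation and polycomb genes had 0 of 10 called in limma (4 higher adjusted over the list alone, camera adjusted p = 0.0326, adjusted p = 0.262 with an estimated correlation), lost without 0 h replicate 2 or 24 h replicate 2 (medians 0.20 and 0.28). Fibroblast genes fell at 1 of 21 (camera adjusted p = 0.0463, adjusted p = 0.472 with an estimated correlation), lost without 0 h replicate 2 or 24 h replicate 1 (medians -0.17 and -0.24). Genes chosen as higher in F-class than C-class clones or than ESC, not independent evidence of a direction, each had 12 lower (camera adjusted p = 4.4e-10 and 4.5e-09, adjusted p = 0.262 and 0.180 with an estimated correlation). Every gene named for 24 h lost its call without at least 1 array. The count was 8 without 0 h replicate 1 and 0 in limma without 0 h replicate 2, 24 h replicate 1 or 24 h replicate 2, where 1035, 1010 and 993 genes had an unadjusted p under 0.05.

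The difference between 48 h and 24 h was tested directly and had 1688 called genes, 854 higher and 834 lower at 48 h. The fragile-X neighbour gene Fmr1nb was at least 58.3-fold higher and the testis lactate dehydrogenase Ldhc at least 19.7-fold higher. Eras rose 11.6-fold (adjusted p = 0.00083) and Sox2 5.87-fold (adjusted p = 0.00049), while Esrrb (log2 fold change 2.22, adjusted p = 0.15), Dppa5a (4.71, adjusted p = 0.099) and Cdh1 (0.89, adjusted p = 0.16) did not pass. The neuropeptide gene Npy and the embryonic globin Hbb-y were 17.2-fold and 15.3-fold lower, both lost without either 24 h array (log2 fold change -4.13 and -4.08 for Npy, -3.88 and -3.99 for Hbb-y) or 48 h replicate 2 (-3.23 and -2.41). Hoxa9 was 10.7-fold lower. Epithelial genes rose at 8 of 17 (11 adjusted over the list alone, median 1.54), germline genes at 4 of 6 (median 2.98), pluripotency genes at 7 of 23 with 1 lower (8 and 1 adjusted over the list alone, median 0.53) and the reprogramming factors at 2 of 4 (3 adjusted over the list alone, median 0.99). Fibroblast genes fell at 7 of 21 (9 adjusted over the list alone, median -0.78) and p53 genes at 5 of 11 (6 adjusted over the list alone, median -0.88). The camera adjusted p values were 4.4e-05, 9.0e-05, 0.00681, 0.0205, 2.2e-05 and 9.8e-04 (adjusted p = 0.438, 0.193, 0.239, 0.182, 0.182 and 0.182 with an estimated correlation). The count of genes was 545, 507, 752 and 451 without 24 h replicate 1, 24 h replicate 2, 48 h replicate 1 and 48 h replicate 2.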

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

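Both tests of number format and the test of a mixture with C-class-like cells were chosen after the result was seen. Of 32 quantities examined in the 6 F-class clones, 0 had a clone further from the rest than Dixon's critical value, where chance would give 1.6. Among 100 splits of the 28 clones into 6 and 22, only the labelled split, 1 of 100, called as many as 2727 genes. The highest other split called 554 and held 4 of the F-class clones among its 6, so no other split drawn came near the labelled count. With 100 splits the share cannot fall below 1 of 100. A class assigned from expression would give such a count as well, and how clones were assigned is not stated in the labels.

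ESC replicate 1 had higher immune and fibroblast transcripts than ESC replicate 2, with an immune list mean of 10.80, against at most 8.51 on the other 30 arrays of its number format. Number format is argued against for the immune genes, since those 30 arrays, which are clones and primary fibroblasts, stood at most 1.46 above ESC replicate 2 in the median gene, against 4.76 for ESC replicate 1, and it stays open for the fibroblast genes, as the fibroblast arrays differ in source as well as in format, with the macrophage gene C1qb at 4.80 and 9.58. Of 10 macrophage genes in no other list, 10 (100%) were over 2-fold higher in ESC replicate 1, with a median difference of 3.61, among them Mrc1 (10.44 and 7.04), Fcgr3 (11.32 and 4.80) and C1qb (10.78 and 4.57), so RNA of macrophages is a candidate explanation, though Fcer1g and Ptprc stayed at the floor on both arrays. RNA of fibroblasts cannot be told apart from other causes, since 78% of 200 fibroblast-specific genes were higher in ESC replicate 1, between the bounds set beforehand, while 86.5% and 84.5% were higher in the iPSC arrays than in ESC replicate 2. No biological explanation was tested.

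Of 8 mesoderm genes 4 and of 7 endoderm genes 3 were called higher in iPSC than in ESC, and these 7, picked because they were called, were higher on both iPSC arrays than on both ESC arrays, while the endoderm median was -0.16 (0.42 against the ESC array of the same format). Number format does not account for it, as the mesoderm median was 2.53 against the ESC array of the same format, where 6 of the 7 were called and Mesp1 was not. RNA of fibroblasts is argued against too, since 0 of the 7 (0%) were higher in a fibroblast array than in iPSC, though Gata6 was 8.59 and 8.26 in fibroblasts, against 9.35 and 8.81 in iPSC. Evx1 was not particular to iPSC, at 9.20 and 9.29 there and at means of 9.44 in C-class and 8.06 in F-class clones. The rest of the 7 had means of 6.00 or lower in both classes of clone. A hypothesis left open is that some iPSC had begun to differentiate, which may also hold of a difference in culture, and neither was tested. With 2 lines from different origins, and list calls that ended without ESC replicate 2 (medians 1.54 for mesoderm and -0.51 for endoderm), it rests on few arrays.

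Genes higher in C-class than in F-class clones were higher in F-class cells at 48 h of HDACi, with a median of 1.32. With no untreated array at 48 h, the inhibitor cannot be told apart from time in culture. A general rise of dim genes is argued against, since lists matched on the 0 h level had medians whose central 95% ended at 0.19 and whose maximum was 0.28 over 10000 draws. A mixture with cells like the C-class clones, or their outgrowth, stays open for these genes. The lower 48 h array had a pluripotency mean 0.43 above the highest C-class clone (11.03 and 10.61), but the clones themselves had an SD of 0.90, so a gap of that size excludes nothing. No biological explanation was tested.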

How the results depend on the processing

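Number format as a term and the shift by it were tests chosen after seeing the data, and the cause of a change was not tested except where fewer arrays or a stricter requirement explain it. Over all settings, 8987 of 10149 checks of named genes and 2500 of 2857 checks of lists kept their direction and side of the threshold, 1020 and 144 weakened, 108 and 89 strengthened, 9 and 7 reversed, and 25 and 117, not called to begin with, moved to the other side of 0. For a list, direction here is the sign of its median, which can differ from the direction of its test. F-class against C-class stayed within 1.5 times of 2727 in 14 of 15 settings. A 2-fold requirement left 649 there, 2579 and 2104 for F-class and C-class against ESC, 3898 and 3763 against fibroblasts, 444 for iPSC against ESC, 2956 for F-class against iPSC, 837 for Myc, 1722 for HDACi at 48 h and 1079 for 48 h against 24 h. It also turned the balance to lower against fibroblasts (1922 higher and 1976 lower for F-class, 1825 and 1938 for C-class) and for F-class against iPSC (1383 and 1573). For Myc it turned to higher (468 and 369). A variance for each group gave 2039 (F-class against ESC), 1335 (C-class against ESC), 4234 (C-class against fibroblasts) and 122 (iPSC against ESC). Number format as a term, estimated from the ESC and fibroblast pairs alone, gave 400 (iPSC against ESC) and 2707 (F-class against iPSC). The replicate block gave 2553 for Myc, where the line pairs the arrays. It ended the interferon and stress list calls and added calls of Nanog and Pou5f1, and it changed the call of no other gene or list named with the Myc results. HDACi arrays share only a number (correlations of deviations 0.26, 0.09 and 0.08), and the block gave 523 at 24 h, 3876 at 48 h and 2545 for 48 h against 24 h. Fitting 1 experiment alone, without a block, gave 0 for Myc in limma (1559 at an unadjusted p under 0.05), 1756 at 24 h, 4997 at 48 h and 3804 for 48 h against 24 h, and quantile normalization gave 337 at 24 h. Leaving out single arrays, where a lone array is assumed to vary like the other groups, gave 3306 to 4271 (C-class against ESC), 389 to 2003 (iPSC against ESC, 2003 without ESC replicate 2), 890 to 2078 (Myc), 0 to 8 (24 h, where limma had 993 to 1093 at an unadjusted p under 0.05), 1227 to 1611 (48 h) and 451 to 752 (48 h against 24 h). With an estimated correlation 2 of 84 list calls held. The day 18 pluripotency median of 1.84 was 0.72 with quantile normalization, 0.81 with the authors' values, 0.53 with no detection filter and 1.15 with a stricter one, and the day 18 share nearer F-class was 89.5% when shifted by the format difference.

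Leaving out single arrays reversed Tyrobp (-5.19 to 0.056) and Adgre1 (-3.99 to 0.28) in F-class against ESC and Tyrobp (-5.02 to 0.23) and Adgre1 (-3.96 to 0.32) in C-class against ESC, each at the end without ESC replicate 1. In iPSC against ESC it reversed F13a1 (-6.27 to 0.18), Tyrobp (-5.12 to 0.13) and the medians of the immune list (-4.51 to 0.078), the endoderm list (-0.51 to 0.62) and the fibroblast list (-0.013 to 1.42). The endoderm median there, -0.16, was also 0.023 with no detection filter and 0.22 with number format as a term, and that of F-class against iPSC was 0.16 under the stricter filter, where its call was lost. In iPSC against ESC the endoderm test had pointed higher despite its negative median, so a positive median there does not reverse that call. Kdr in C-class against fibroblasts was -0.20 to 1.36 without single arrays and -0.052 with number format as a term, and Asns in F-class against iPSC was -0.25 with it. A fit with slides as a block was not run because slides are not named in the sources used here. Between 46.6% and 53.4% of probes stood above background per array, which leaves dim genes with bounds only.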

Other observations

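The overlap below was counted after the results were seen. Esrrb and Dppa5a, chosen after their values were seen, differed among F-class clones. Esrrb was 8.51, 10.10 and 9.50 and Dppa5a 10.69, 9.75 and 12.04 in clones 6, 13 and 27, against Esrrb of 5.55, 6.39 and 6.02 and Dppa5a of 5.08, 6.56 and 5.66 in clones 1, 2 and 7. Zfp42 differed less, at 7.75, 7.58 and 8.09 against 7.48, 6.46 and 6.72. Nanog lay between 11.14 and 11.85 in all 6, against 5.22 to 11.32 in C-class clones. The F-class cells before HDACi differed in the same 2 genes, with Dppa5a at 13.00 and 6.55 and Esrrb at 10.44 and 7.19.

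The Tet-Myc and HDACi comparisons share no arrays. Of 10154 genes, 228 were higher both without doxycycline and at 48 h of HDACi, where independence would give 106.15, and genes lower in both were 1.82 times as many as the 116.24 that independence would give. Genes that went opposite ways numbered 90 (108.29) and 82 (113.94). Both experiments went through 1 fit with a pooled variance, so genes with a small variance are called more easily in both, and the overlap was not tested. Both comparisons also lack an untreated or unwithdrawn array at 48 h, so they share time in culture.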
